A study of Mus musculus with 44 samples.

How the data were processed

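H3K9me3 CUT&Tag was measured in 44 libraries of female mouse embryonic stem cells, in 14 groups and 4 experiments. The authors' processing notes name Trim Galore 0.6.10, Bowtie2 2.5.0, SAMtools 1.22, bedtools, deepTools 3.5.6 and SICER, and the mm10 build. The deposited files list 1 library's islands each, in the column layout of the island caller epic2, with raw counts of reads or fragments per island and the caller's score per island. Caller parameters, the mapping filter and any duplicate removal are not given in the sources used here, so reads from near-identical copies, as in Zfp clusters or receptor families, cannot be separated. Deposited scores were used for ranks within a library only. Spike-in DNA named in the labels' protocol was not used, so a change in the total amount of H3K9me3 was not measured.

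Islands of the libraries of an experiment were merged into consensus regions: 134904 for CasTuner day 3 (12 libraries), 117805 for CasTuner day 4 (12), 114877 for split dCas9-KRAB (9) and 118930 for F121.9 (11). The counts of a library's islands in a region were summed, and a region without an island counted as 0. Library size was the sum of island counts, scaled by TMM, and CPM are on that scale. Regions passed to the test if they had an island in at least as many libraries as the smaller group holds and passed filterByExpr. The edgeR 4.0.16 quasi-likelihood test was run per comparison on a fit of all groups of the experiment, with Benjamini-Hochberg adjustment and a threshold of 0.05. DESeq2 1.42.0 was the other tool, and camera of limma 3.58.1 tested gene lists, with a preset correlation of 0.01 and with the correlation estimated. Log2 fold changes are given with the SE of the fit, and other errors are SD. Where a group had no island in any library, CPM are given and no fold. Medians of lists use fitted values, which for such regions depend on the prior count.

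Windows of 2 kb on either side of the start of Xist and of each targeted gene were measured as island reads per 1000000 island reads (RPM), with counts of an island shared out by overlap. They were compared on log2 of RPM plus 1 by exact two-sided permutation tests of the difference of means. With 3 libraries against 3 the smallest p is 0.1, with 3 against 4 it is 0.0571 and with 4 against 4 it is 0.0286, so comparisons of groups of 3 cannot pass a threshold of 0.05. The annotation of 49943 genes on GRCm38.p6, the assembly of mm10, carries no strand, and strands of the targeted genes and Xist were taken from general knowledge. For the same reason, regions were assigned to genes with 2 kb on both sides of the gene, while the design had named 2 kb upstream. Exons and introns were not resolved.

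The 15 gene lists were the X inactivation centre, targeted regulators, imprinted genes, germline genes, 2-cell genes, naive pluripotency, primed pluripotency, other lineages, housekeeping genes, Zfp zinc finger genes, protocadherin clusters, olfactory and vomeronasal receptors, Hox genes, the Rhox cluster and Mage genes. The names Nespas, Dub1, Pramef25 and Oct6 had no match in the annotation. Lists, tests, groups, alternatives and the rule for naming regions were fixed before the data were examined, except where a setting is said to have been chosen later. The rule named Xist and the targeted gene in every comparison, then the 10 called regions with the largest log2 fold change in each direction whose CPM did not overlap between groups, then 2 to 4 called members per list by smallest adjusted p. Where no region passed, it named the 3 with the smallest p in each direction. Regions were named by overlapping protein-coding or lncRNA genes, or by the nearest with its distance. Zfp33b, Zfp808, Olfr53, the medians along chromosomes 12 and X and Pgk1 fall outside this rule and were picked out after their values were seen.

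Same-numbered libraries of the Zic3 comparison correlated above 0.1 in every pair (0.106, 0.128 and 0.166), and a fit with the number as a block called 0 regions there, as did the fit without it (1575 and 1189 at an unadjusted p under 0.05). In no other comparison did every same-numbered pair pass 0.1. In the Rex1 and Zfp281 comparisons each library still correlated best with its own number (0.0262 to 0.0844 and 0.0247 to 0.0651). The block gave 143 regions in place of 211 for Rex1 and 888 in place of 484 for Zfp281. A pairing by number is thus not excluded there, and the main fits leave it out.

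Alternatives were RLE size factors, library size without TMM, DESeq2, no filterByExpr, an island required in every library of the compared groups, a fit of the compared groups alone, the replicate number as a block, a stricter caller threshold (the 25% of islands with the lowest score dropped), 10 kb bins, windows of 1 and 5 kb, a pseudocount of 0.1, a region counted as present when an island covers at least 50% of it, covered length in place of reads, and each library left out in turn. The tests were also run on simulated data, with 200 changed regions added to each comparison. Of 4-fold changes, 41.8 to 88.1% were recovered, and of 2-fold changes 1.5 to 26.9%, with 0 to 2 false calls. All simulated regions shared 1 dispersion, the median over regions with an island in every library. Changed regions were drawn from all but the 25% with the lowest mean. Regions that lack islands in some libraries may vary more, so these rates do not measure recovery or false calls there. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used. Depth ranged from 735242 to 1990837 island reads in CasTuner day 3, from 235144 to 2149853 in CasTuner day 4, from 2509761 to 3670771 in split dCas9-KRAB and from 901805 to 3147241 in F121.9. No library was left out.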

Results

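Trimethylation of histone H3 at lysine 9 (H3K9me3), a mark of heterochromatin, was profiled by CUT&Tag in 44 libraries of differentiating female mouse embryonic stem cells. The series asked how regulators of Xist, the noncoding RNA that coats and silences the inactive X chromosome, affect heterochromatin at the Xist promoter. The regulators were Rnf12 (Rlim in the gene table), an X-linked E3 ubiquitin ligase that marks REX1 for degradation, Rex1 (Zfp42 in the gene table), a zinc finger repressor of naive pluripotent cells, the zinc finger proteins ZIC3, ZFP280C and ZFP281, and the RNA-binding protein ZFP36L1. The 14 groups held 3 or 4 libraries each and formed 4 experiments. CasTuner, a dCas9 repressor that is degraded while the ligand dTAG-13 is present, was used in TX1072 cells, a CAST by C57BL/6 hybrid line, and each of its 4 knockdowns (0 nM dTAG-13) had its own control (500 nM). Split dCas9-KRAB, assembled with 100 µM abscisic acid, was used in TX1072 cells against Rex1 and Zfp281, with safe-targeting control (STC) guides as the reference. The F121.9 line, from a cross with Cast/EiJ mice, was compared with a line lacking Rnf12 and with a line lacking both Rnf12 and Rex1 (double knockout). Rnf12 and Zic3 knockdowns and their controls were harvested on day 3 of differentiation and all other groups on day 4.

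Each deposited file lists the H3K9me3 islands of 1 library with the reads in each. The libraries held 23675 to 82099 islands with 235144 to 3670771 island reads, and islands covered 27.0 to 127 Mb. The day 4 CasTuner libraries differed most in depth, from 235144 to 2149853 island reads, and replicate 1 of each of its 4 groups held 235144 to 294369. An island below the caller's threshold is not listed, so a value of 0 here means that no island was called and sets no upper limit on the reads. At 15 housekeeping genes with 2 kb on either side, the background in the 44 libraries was a median of 0.368 island reads per 1000000 island reads (RPM) per 4 kb, and a median of 2 of the 15 genes overlapped an island. Labels number the replicates without saying that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Each knockout genotype is 1 cell line.

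**Figure D1:**
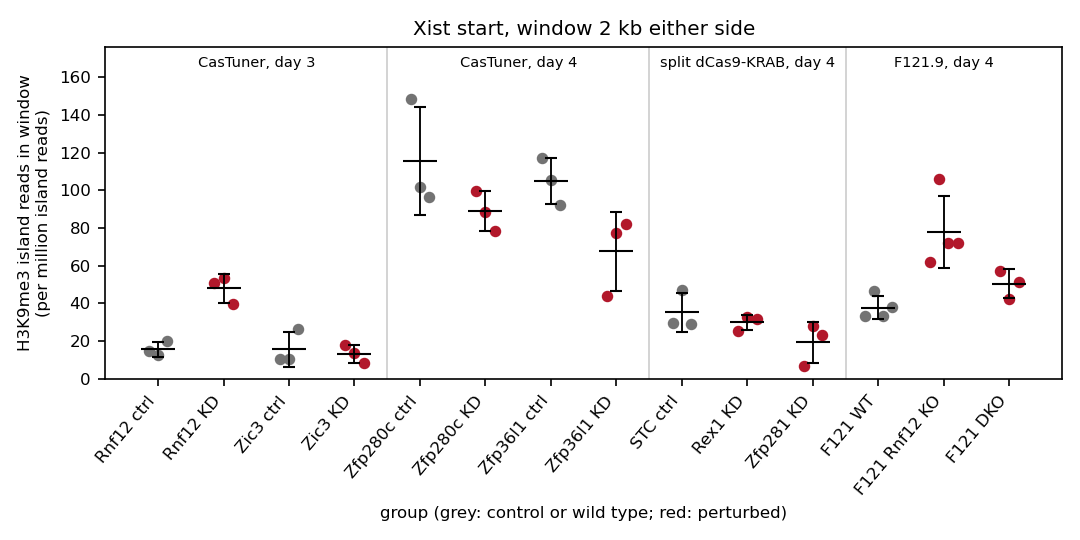
H3K9me3 RPM (island reads per 1000000) in the window 2 kb on either side of the Xist start (vertical axis), for every library (points) of the 14 groups (horizontal axis), with the group mean and SD (black bars); grey points are control or wild-type libraries. All 3 Rnf12 knockdown libraries lay above all 3 of their controls (means 47.9 and 15.7), and all 4 Rnf12 knockout libraries above all 4 wild-type libraries (means 78.0 and 37.8).

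At the Xist promoter on day 3, the mean H3K9me3 signal of the Rnf12 knockdown was 3.05 times that of its control, and DESeq2 called the region over the Xist start while edgeR and the permutation test did not. In the window 2 kb on either side of the Xist start (mm10, chromosome X, 103481233 to 103485232, which overlaps the interval of Tsix, the antisense gene), island reads were 47.9 ± 7.47 RPM in the knockdown and 15.7 ± 3.94 in the control (SD, n = 3 each). Islands covered 69.7% of the window in the knockdown and 23.3% in the control, on average. Reads outside islands are not listed, so the ratio of 3.05 also reflects how much of the window was called. All 3 knockdown libraries lay above all 3 controls (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows; adjusted p = 0.171 over the 9 comparisons of this window). In edgeR's fit of all regions, the region over the Xist start (X, 103483201 to 103488200) had a log2 fold change of 2.89 ± 0.84 (SE) with an adjusted p of 0.726. DESeq2 gave 3.00 with an adjusted p of 0.0272, so this region was among its calls, while the other alternatives had an adjusted p of 0.555 to 1.00. The Rlim promoter itself held an island in 0 of 3 knockdown and 1 of 3 control libraries.

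Over all regions, none passed edgeR's test in the Rnf12 knockdown: 0 of 34017 regions had an adjusted p under 0.05, while 1622 had an unadjusted p under 0.05 and DESeq2 called 151. The regions with the smallest p included Arl15, a small GTPase gene (13, 113800801 to 113808200), at 59.7 ± 3.37 counts per 1000000 after TMM scaling (CPM) in the knockdown against 21.6 ± 5.52, and Pde7a, a cAMP phosphodiesterase gene, at 58.7 ± 10.8 against 12.1 ± 3.65 CPM. Both had an adjusted p of 0.187. Lower in the knockdown, without passing, were a region near Ugt8a (3, 126136001 to 126143200; 11.6 ± 4.02 against 36.0 ± 0.670 CPM) and one near Adamts20 with no island in any knockdown library. Of the fixed gene lists, the set test camera with a preset correlation placed Zfp zinc finger genes (184 regions, median log2 fold change 0.46, adjusted p = 4.6e-09), protocadherin clusters (9 regions, 1.33, adjusted p = 0.00133), imprinted genes (14 regions, 0.58, adjusted p = 0.000218) and the X inactivation centre (9 regions, 0.52, adjusted p = 0.00156) above other regions. None of these 4 calls held with an estimated correlation (adjusted p = 0.118 for the first 3 lists and 0.144 for the X inactivation centre), and no member passed over all regions. Adjusted over the list alone, 5 Zfp regions were higher and 1 lower, 2 protocadherin regions were higher, 1 imprinted region was higher and 2 regions of the X inactivation centre were higher. Leaving out knockdown replicate 1 or 3 or control replicate 2 gave 2, 1 and 3 regions.

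In the Zic3 knockdown the mean signal at the Xist promoter was 0.845 times that of its control, without passing a test. Island reads in the Xist window were 13.2 ± 4.84 RPM in the knockdown and 15.7 ± 9.24 in the control (n = 3 each; exact permutation p = 0.8, adjusted p = 0.8). The Zic3 promoter held no island in any of the 6 libraries. Of 33481 regions, edgeR called 0, with 1189 at an unadjusted p under 0.05, and DESeq2 called 125. The smallest p belonged to regions near Sc5d, a sterol desaturase gene (9, 42200001 to 42204600), and Tcf7l2, a transcription factor of Wnt signalling (19, 56103001 to 56108800). These held 20.6 ± 2.36 and 20.2 ± 11.9 CPM in the controls and no island in any knockdown library (adjusted p = 0.0685 for both). Among higher regions, the smallest p belonged to a region in Cdh13, which encodes T-cadherin (8, 118798201 to 118804800), with 142 ± 10.2 CPM and a log2 fold change of 0.96 ± 0.18 (adjusted p = 0.176). Imprinted genes (12 regions, median log2 fold change 0.29, adjusted p = 0.0123) and Zfp zinc finger genes (173 regions, 0.12, adjusted p = 0.00537) ranked above other regions by camera with a preset correlation, but not with an estimated one (adjusted p = 0.437 and 0.467). No member passed over all regions or adjusted over the list alone. Leaving out knockdown replicate 3 gave 22 regions and leaving out control replicate 2 gave 1, and 2 omissions, of knockdown replicate 3 or of control replicate 3, turned the sign of the Xist window.

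In the Zfp280c knockdown H3K9me3 fell at 28 of 34626 regions and rose at 0 (edgeR, adjusted p under 0.05; DESeq2 called 99). Of the 28, 8 overlapped Zfp zinc finger genes and 10 lay on chromosome 12. At Zfp930 (8, 69219001 to 69224600) the controls held 48.4 ± 15.6 CPM and no knockdown library had an island (adjusted p = 0.000198). At Zfp951 a 36 kb region (5, 104804801 to 104840800) fell by 1.63 ± 0.21 on the log2 scale, from 638 ± 71.9 to 202 ± 68.1 CPM (n = 3 each; adjusted p = 0.000722). Within the interval of Kcnq1, a potassium channel gene whose imprinting depends on the antisense RNA Kcnq1ot1, a region at 7, 143243001 to 143256400 fell by 1.05 ± 0.20, from 301 ± 56.8 to 145 ± 25.1 CPM (adjusted p = 0.0374). A loss on chromosome 12 (21750601 to 21754600) lay 182683 bp from the gene model LOC115487949, with 26.4 ± 4.96 CPM in the controls and no island in any knockdown library.

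By list, 8 of 290 regions at Zfp zinc finger genes fell in the Zfp280c knockdown and 0 rose (22 fell adjusted over the list alone), with a median log2 fold change of -0.49. Camera with a preset correlation gave an adjusted p of 2.6e-21, and with an estimated correlation an adjusted p of 0.80. The other members that fell included Zfp33b, at -1.29 ± 0.21, and Zfp808, at -2.58 ± 0.45. Of 37 imprinted regions, 2 fell, both at Kcnq1 and Kcnq1ot1. The Xist window held 89.0 ± 10.7 RPM in the knockdown and 116 ± 28.6 in the control (n = 3 each; exact permutation p = 0.2, adjusted p = 0.257), and the Zfp280c promoter no island. Fitting the 2 groups alone, or only replicates 2 and 3 of every group, gave 0 regions in place of 28.

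In the Zfp36l1 knockdown the mean signal at the Xist promoter lay below that of the control, without passing a test. The Xist window held 67.7 ± 20.9 RPM in the knockdown and 105 ± 12.3 in the control, 0.645-fold (n = 3 each), and all 3 knockdown libraries lay below all 3 controls (exact permutation p = 0.1, the smallest possible; adjusted p = 0.171). The region that spans the Xist start (X, 103475201 to 103492000) had a log2 fold change of -0.79 ± 0.28 with an adjusted p of 1.00 (edgeR). No region passed: 0 of 33822, with 584 at an unadjusted p under 0.05 and 0 by DESeq2. Among the smallest p were those of a region near Lmcd1 (6, 112215001 to 112218200), with 20.7 ± 13.5 CPM in the controls and no island in any knockdown library, and of Plekha2 (8, 25102401 to 25111800), with 27.9 ± 32.9 against 158 ± 82.5 CPM. The 3 regions at genes of primed pluripotency had a median of -0.89 (camera adjusted p = 0.0482, and 0.970 with an estimated correlation), and 299 Zfp regions -0.24 (adjusted p = 0.0133, and 0.970 with an estimated correlation). Mitochondrial islands held 5.12 ± 2.67% of island reads in the knockdown against 2.43 ± 0.552% in the control.

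**Figure D2:**
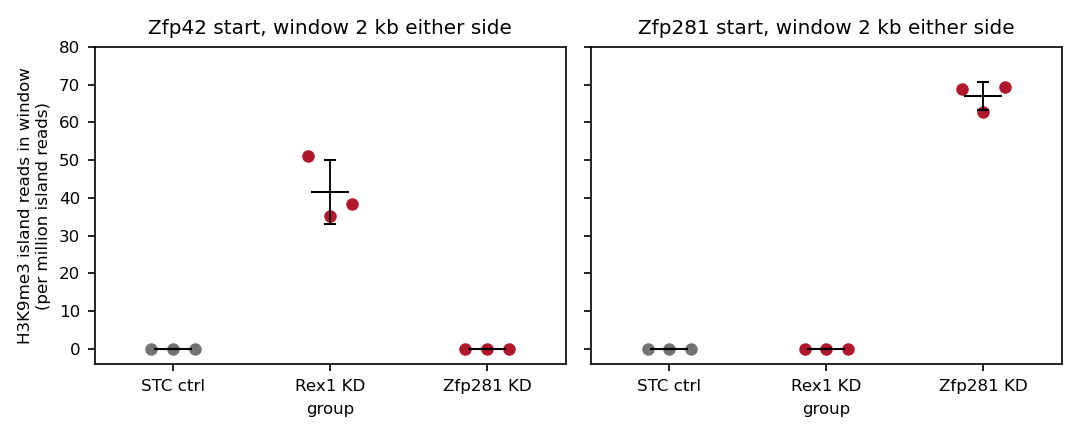
H3K9me3 RPM (island reads per 1000000) in the windows 2 kb on either side of the Zfp42 start (left) and the Zfp281 start (right) for the 9 split dCas9-KRAB libraries (points), with the mean and SD of each group (black bars). The Zfp42 window held 41.6 RPM on average in the Rex1 knockdown and the Zfp281 window 67.0 RPM in the Zfp281 knockdown, and neither held an island in any of the 3 STC libraries.

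Targeting Rex1 with split dCas9-KRAB was accompanied by a new H3K9me3 domain at its gene and by 206 other gained regions. The Zfp42 promoter window held 41.6 ± 8.43 RPM in the knockdown (n = 3) and no island in any of 3 STC libraries (exact permutation p = 0.1, the smallest possible). The domain over Zfp42 (8, 43299401 to 43312400) spanned 13.0 kb with 96.2 ± 8.01 CPM (edgeR adjusted p = 0.000463). Of 55064 regions, 207 rose and 4 fell, and 163 of those that rose had no island in any STC library. The highest was a region on chromosome 1 (190512801 to 190531200), 241678 bp from Rps6kc1, with 288 ± 24.4 CPM. Others lay within Akap13, an anchoring protein and Rho exchange factor gene (7, 75482601 to 75494600; 80.7 ± 6.86 CPM), within Car10 (87.9 ± 14.7 CPM), within Enox1 (59.2 ± 5.08 CPM) and 24512 bp from Malt1, which encodes a paracaspase of lymphocyte signalling (104 ± 14.7 CPM). None of these had an island in any STC library.

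The 4 regions that fell in the Rex1 knockdown lay at Hhex, a homeobox gene (19, 37440401 to 37444800), which fell by 2.18 ± 0.29 on the log2 scale, at Myl12a, a myosin light chain gene, at Prkn, the parkin ubiquitin ligase gene, and near Stmn2. The last 3 had no island in any knockdown library. At Olfr1205, an olfactory receptor gene, a region rose by 1.54 ± 0.20 (28.4 ± 1.81 against 9.72 ± 0.626 CPM; adjusted p = 0.0179), the 1 call among 566 olfactory and vomeronasal receptor regions. Regions at Zfp zinc finger genes (350, median log2 fold change -0.20) ranked below other regions by camera with a preset correlation (adjusted p = 5.6e-05; adjusted p = 0.338 with an estimated correlation), with Zfp42 itself the 1 member that passed. The naive pluripotency list (5 regions) ranked above other regions (adjusted p = 3.4e-07, and 0.0406 with an estimated correlation) through Zfp42, its 1 member that passed, while its median was -0.25. The replicate block ended this call (adjusted p = 0.430). The list of the targeted genes (2 regions) ranked above other regions too (adjusted p = 8.8e-20, and 0.000947 with an estimated correlation), again through Zfp42, the guides' own target and the 1 member that passed, with 1 region higher and 1 lower adjusted over the list alone. Imprinted genes ranked lower (30 regions, median -0.30, adjusted p = 0.0413, and 0.338 with an estimated correlation). The Xist window held 30.0 ± 4.02 RPM against 35.2 ± 10.3 in STC (n = 3 each; exact permutation p = 0.6, adjusted p = 0.675), and leaving out STC replicate 2 turned the sign. Leaving out Rex1 knockdown replicate 1, 2 or 3 left 30, 29 and 36 regions in place of 211, and requiring an island in every library of both groups left 30.

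Targeting Zfp281 likewise was accompanied by an H3K9me3 domain at its gene, and H3K9me3 over the Xist gene was lower, in a call that several settings ended. The Zfp281 promoter window held 67.0 ± 3.67 RPM in the knockdown and no island in any STC library (n = 3 each; exact permutation p = 0.1). The region over Zfp281 (1, 136621201 to 136628200) held 98.5 ± 9.51 CPM (edgeR adjusted p = 0.00158). Within Xist and Tsix, a region at X, 103476201 to 103482800 fell by 1.54 ± 0.22 on the log2 scale, from 73.3 ± 20.0 to 25.2 ± 5.11 CPM (adjusted p = 0.0214). Fitting the 2 groups alone ended this call (-1.55, adjusted p = 0.101), as did leaving out any library but STC replicate 3 (-1.34 to -1.65, adjusted p = 0.0597 to 0.106). The neighbouring region over the Xist start (103483001 to 103491000) had a log2 fold change of -0.91 ± 0.20 and did not pass (adjusted p = 0.0670). It passed with DESeq2 (adjusted p = 7.8e-05), with an island required in every library (adjusted p = 0.0197) and with the replicate block (adjusted p = 0.0214), and in no other alternative (adjusted p = 0.0616 to 0.216). The Xist window held 19.3 ± 10.9 RPM against 35.2 ± 10.3, 0.547-fold, with all 3 knockdown libraries below all 3 STC libraries (exact permutation p = 0.1, the smallest possible; adjusted p = 0.171).

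Of 53860 regions, 163 rose and 321 fell in the Zfp281 knockdown, and 106 of those that fell had no island in any knockdown library. Gains with no island in STC lay within Tns3, a tensin gene (11, 8572401 to 8576800; 18.4 ± 2.88 CPM), within the Ugt1a cluster of glucuronosyltransferases (17.0 ± 5.14 CPM) and within Gpa33 (9.54 ± 1.73 CPM). Losses with no island left in any knockdown library lay within Dcc, the netrin receptor gene (18, 71602601 to 71605400; 15.8 ± 0.454 CPM in STC), within Svop (17.5 ± 5.38 CPM) and within Repin1 (17.4 ± 4.21 CPM). Zdhhc15, in the X inactivation centre list, fell by 1.57 ± 0.18 (adjusted p = 0.0108). At Kcnq1 and Kcnq1ot1, 2 regions fell, by 0.89 ± 0.13 and 1.37 ± 0.22.

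Among regions at Zfp zinc finger genes, 20 of 346 fell and 2 rose in the Zfp281 knockdown (64 and 4 adjusted over the list alone), with a median log2 fold change of -0.46. Camera gave an adjusted p of 1.4e-08 with a preset correlation and an adjusted p of 0.196 with an estimated correlation. Examples were Zfp958, which fell by 1.33 ± 0.12, and Zfp612, which fell by 1.65 ± 0.20. Protocadherin clusters (20 regions, median -0.89) also ranked below other regions (adjusted p = 0.00282, and 0.561 with an estimated correlation), with 0 members passing over all regions and 6 lower adjusted over the list alone. The X inactivation centre (11 regions, median -0.67) had an adjusted p of 0.00848, of 0.196 with an estimated correlation and of 0.0916 with the replicate block. The list of the targeted genes (2 regions) had an adjusted p of 1.1e-20, of 0.00426 with an estimated correlation and of 0.0916 with the replicate block, through Zfp281, the guides' own target and the 1 member that passed over all regions or over the list alone. Sycp1, of the meiotic synapsis machinery, and Usp17la, a deubiquitinase gene of the 2-cell list, held no island in any knockdown library (9.10 ± 4.00 and 5.81 ± 2.96 CPM in STC). Leaving out knockdown replicates 1, 2 and 3 in turn left 46, 216 and 159 regions in place of 484, and leaving out STC replicates 1, 2 and 3 left 13, 36 and 144. Without STC replicate 2 more regions rose (23) than fell (13), and without STC replicate 1 there were 6 and 7. Fitting the 2 groups alone left 1 region, that over Zfp281 itself, and 0 that fell.

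In F121.9 cells without Rnf12, H3K9me3 rose over the start of Xist. Its window held 78.0 ± 19.13 RPM in the knockout and 37.8 ± 6.20 in the wild type (n = 4 each), 2.06-fold, and all 4 knockout libraries lay above all 4 wild-type libraries (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.171 over the 9 comparisons). The 16 kb region over the Xist start (X, 103475001 to 103491000) rose by 1.44 ± 0.20 on the log2 scale, from 88.8 ± 25.5 to 240 ± 52.5 CPM (edgeR adjusted p = 0.00186). Within Tsix, at X, 103447001 to 103448800, the knockout held 15.8 ± 4.41 CPM and no wild-type library had an island. Zdhhc15 rose by 1.63 ± 0.34. The Rlim promoter window held islands in 3 of 4 knockout and 2 of 4 wild-type libraries (exact permutation p = 0.229). Islands list only enriched stretches, so a deleted exon leaves no trace in them.

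Imprinted genes, which are expressed from 1 parental copy, gained H3K9me3 in the Rnf12 knockout. Of 28 imprinted regions, 12 rose and 0 fell (15 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.66 (camera adjusted p = 3.5e-17, and 0.0220 with an estimated correlation). At H19, a growth-restraining noncoding RNA gene (7, 142576401 to 142584400), the knockout held 69.6 ± 11.4 CPM, at Mest 48.4 ± 13.3 CPM, and at Nnat, which overlaps Blcap, 31.4 ± 1.95 CPM, with no island in any of 4 wild-type libraries at these 3 genes. At Kcnq1 and Kcnq1ot1 (7, 143259201 to 143293200) H3K9me3 rose by 1.73 ± 0.25, from 107 ± 45.3 to 359 ± 83.7 CPM. The 8 other regions lay at Meg3, Airn, Igf2, Nnat and Kcnq1, several of them at Kcnq1. The regions at Kcnq1 and Kcnq1ot1 are neighbours between 143180001 and 143293200 of chromosome 7. The count of 12 and the preset correlation treat such neighbours as separate members, although they are not independent. Meg3 lies in an interval of chromosome 12 (100 to 110 Mb) whose median rose by 0.79. The X inactivation centre list ranked above other regions, with 3 of 8 regions passing (5 adjusted over the list alone) and a median of 1.16. Its camera adjusted p was 4.4e-06 (0.0220 with an estimated correlation). This list covers the regions at Xist, Tsix and Zdhhc15 given above, so its calls are not independent of those.

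Genome-wide, 748 regions rose and 403 fell of 32142 in the Rnf12 knockout. Gains with no wild-type island lay within Zfp609 (33.7 ± 12.6 CPM) and within Abca7, a lipid transporter gene (32.0 ± 16.3 CPM). Losses with no knockout island lay within Nkx2-1, a homeobox gene of lung, thyroid and forebrain (12, 56535601 to 56540600; 36.4 ± 15.4 CPM in the wild type), in an interval of chromosome 12 (50 to 60 Mb) with a median of -0.38, and within Clec2g, a C-type lectin gene (17.1 ± 11.6 CPM). Among 234 Zfp regions 21 rose and 3 fell (34 and 5 adjusted over the list alone), such as Zfp146, which rose by 2.59 ± 0.34, but the list's call (adjusted p = 3.2e-08) was lost with an estimated correlation (adjusted p = 0.294). Hoxb3 rose by 2.18 ± 0.35, and 7 of 276 olfactory and vomeronasal receptor regions rose, such as Olfr1245, by 1.42 ± 0.22. Naive pluripotency genes (3 regions, adjusted p = 0.00315, and 0.0694 with an estimated correlation) had 0 members passing over all regions and 2 higher adjusted over the list alone. The count was 725, 693 and 579 without wild-type replicate 1, 3 or 4, and 586 and 646 without knockout replicate 2 or 3. Without knockout replicate 1 more regions fell (592) than rose (492).

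**Figure D3:**
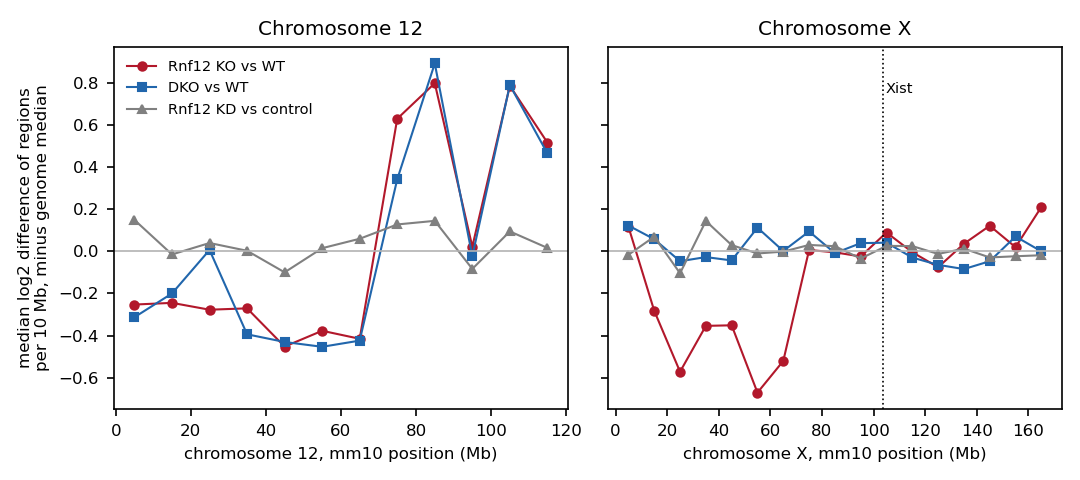
Median log2 difference of the regions in each 10 Mb interval (vertical axis, minus the genome-wide median) along chromosomes 12 (left) and X (right), for the Rnf12 knockout and the double knockout against wild type and for the Rnf12 knockdown against its control. On chromosome 12 both knockout lines lay below 0 between 30 and 70 Mb and reached 0.80 and 0.89 between 80 and 90 Mb.

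Of the 1151 regions that differed in the Rnf12 knockout, 240 lay on chromosome 12, 163 on chromosome X and 748 on other chromosomes. On chromosome 12, 187 regions rose and 53 fell of 1728, and on chromosome X 45 rose and 118 fell of 3093. Medians over 10 Mb intervals were negative from 0 to 70 Mb of chromosome 12, down to -0.45, and positive from 70 to 90 and from 100 to 120 Mb, up to 0.80. On chromosome X they were negative from 10 to 70 Mb, at -0.28 to -0.67, and 0.09 in the interval that holds Xist. Chromosome X held 7.68 ± 0.565% of island reads in the knockout and 8.88 ± 0.498% in the wild type (n = 4 each; exact permutation p = 0.0571, adjusted p = 0.514). With chromosomes 12 and X left out, a setting chosen after seeing these values, 387 regions rose and 166 fell.

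In the double knockout of Rnf12 and Rex1, the mean signal at the Xist promoter lay between those of wild type and Rnf12 knockout. The Xist window held 50.3 ± 7.71 RPM (n = 3), 1.33-fold the wild type (exact permutation p = 0.114, with 0.0571 the smallest possible; adjusted p = 0.171) and 0.645-fold the Rnf12 knockout. All 3 double knockout libraries lay below all 4 Rnf12 knockout libraries (exact permutation p = 0.0571, the smallest possible; adjusted p = 0.171). In edgeR's fit the region over the Xist start rose by 1.01 ± 0.21 against the wild type, from 88.9 ± 25.5 to 180 ± 23.5 CPM (adjusted p = 0.0307), and had a log2 fold change of -0.42 ± 0.21 against the Rnf12 knockout (adjusted p = 1.00). The call against the wild type ended when the 2 groups were fitted alone (1.02, adjusted p = 0.0763) or when any library but wild-type replicate 2 was left out (0.90 to 1.11, adjusted p = 0.0641 to 0.199). The Zfp42 window held no island in any of the 11 F121.9 libraries.

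Against the wild type, 356 regions rose and 21 fell of 33044 in the double knockout. Of the 356, 81 had no island in any wild-type library. Islands covered 103 ± 16.5 Mb in the double knockout (n = 3) and 80.4 ± 20.1 Mb in the wild type (n = 4; exact permutation p = 0.229). Whether this difference in called length shaped the count was not tested. Gains with no wild-type island lay within E2f3, a cell cycle transcription factor gene (13, 29970001 to 29980400; 46.7 ± 9.49 CPM), Cdyl, a chromodomain protein gene (45.3 ± 1.52 CPM), Psme4, a proteasome activator gene (43.0 ± 18.7 CPM), and Polk, the gene of DNA polymerase kappa (26.6 ± 8.27 CPM). Losses lay at Tmem201 (4, 149719801 to 149725200; 40.1 ± 10.8 CPM in the wild type) and Nkx2-1, both with no island in any double knockout library, and the interval that holds Nkx2-1 had a median of -0.45. Mcm5, a replicative helicase gene, fell by 2.47 ± 0.39 and Hmcn1, a hemicentin gene, by 1.37 ± 0.22. Of 23 imprinted regions 7 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.83 and a camera adjusted p of 5.0e-11, or 0.130 with an estimated correlation. Examples were Kcnq1 and Kcnq1ot1 (7, 143259201 to 143293200), which rose by 2.42 ± 0.26, and Mest, at 14.3 ± 3.16 CPM with no wild-type island. Zfp zinc finger genes (10 of 245 rose, 0 fell, 22 and 1 adjusted over the list alone; adjusted p = 5.0e-11, and 0.176 with an estimated correlation) had a median of 0.55, and protocadherin clusters 0.80 (adjusted p = 0.00332, and 0.453 with an estimated correlation). In the X inactivation centre 1 of 8 regions rose (3 adjusted over the list alone; adjusted p = 0.00327, and 0.130 with an estimated correlation), and naive pluripotency genes (2 regions) ranked higher (adjusted p = 0.0203, 0.130 with an estimated correlation and 0.0619 with the replicate block).

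On chromosome 12, 124 regions rose and 8 fell in the double knockout, with interval medians of -0.45 to 0.89, and on chromosome X 11 rose and 0 fell, with medians of -0.05 to 0.11 between 10 and 70 Mb. With chromosomes 12 and X left out, 187 rose and 10 fell. The count of 377 became 583 without wild-type replicate 2, and 171, 107 and 215 without double knockout replicates 1, 3 and 4.

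Between the double knockout and the Rnf12 knockout, edgeR called 2 of 33052 regions, 1664 had an unadjusted p under 0.05 and DESeq2 called 229. A region on chromosome X (25405201 to 25413800), 1108856 bp from the nearest named gene, Slx, held 22.9 ± 4.79 CPM in the double knockout (n = 3) and no island in any of 4 Rnf12 knockout libraries (adjusted p = 0.0108). It lies within 10 to 70 Mb of chromosome X, where the medians of 10 Mb intervals were 0.27 to 0.78 higher in the double knockout (0.61 in its own interval, 20 to 30 Mb). Tmem201 held 36.2 ± 11.8 CPM in the Rnf12 knockout and no island in any double knockout library (adjusted p = 0.000879). Imprinted genes ranked lower in the double knockout (28 regions, median -0.28, adjusted p = 3.5e-06, and 0.215 with an estimated correlation), as did the X inactivation centre (8 regions, median -0.51, adjusted p = 0.00755, and 0.215 with an estimated correlation), with 0 members passing over all regions. Protocadherin clusters ranked higher (18 regions, median 0.68, adjusted p = 0.0487, and 0.711 with an estimated correlation). The count rose to 103 without Rnf12 knockout replicate 1 and was 1 without double knockout replicate 4.

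Lists of germline genes, 2-cell genes, Hox genes, the Rhox cluster, Mage genes, olfactory and vomeronasal receptors, other lineages and housekeeping genes were not called by camera in any comparison in which they had at least 2 tested regions. Their smallest adjusted p was 0.189 for germline genes, 0.0936 for 2-cell genes, 0.0628 for Hox genes, 0.796 for the Rhox cluster, 0.0827 for Mage genes, 0.166 for the receptors, 0.637 for other lineages and 0.443 for housekeeping genes. Among receptor regions in the Zfp281 knockdown 1 rose, at Olfr53, and 4 fell, such as Olfr1312, which fell by 1.51 ± 0.20.

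Counting regions with an island in every library of one group and in none of the other gave 348 gained and 838 lost in the Rnf12 knockdown, 139 and 846 for Zic3, 127 and 171 for Zfp280c, and 222 and 165 for Zfp36l1. The Rex1 knockdown gained 1273 and lost 431, and the Zfp281 knockdown gained 1244 and lost 1214. Against wild type, the Rnf12 knockout gained 220 and lost 455 and the double knockout gained 905 and lost 140, and against the Rnf12 knockout the double knockout gained 756 and lost 33. Such counts carry no test and vary with the grouping: other splits of the same libraries reached 1086, 1747, 3127, 3303, 1112, 866, 693, 1795 and 2550 in the same order, above the real total for Zic3, Zfp280c, Zfp36l1 and all 3 comparisons of F121.9 lines. Mean covered length was 103 Mb in the double knockout, 80.4 Mb in the wild type and 68.6 Mb in the Rnf12 knockout. Whether it shaped the counts of these lines was not tested.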

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

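Among the tests here, those of guide binding, of segment copy number and loss of Rnf12, of imprinted regions and of other splits of the libraries, and the comparison of the regions gained in the Rex1 knockdown with levels in libraries without the proposed cause, were chosen only after the result was seen.

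In the Rlim promoter window, Rnf12 knockout replicate 4 lay apart from its group: it held no island, a log2 value of 0.0, while the nearest library was at 2.80 and the highest at 3.24. Over 6 measures in the 2 groups of 4 libraries, 12 tests in all, 1 library lay apart in this way. In continuous values chance sets apart a library this far in about 1 in 20. Here the 0.0 stands for no called island, so that rate cannot be applied to it. No island was called there in 2 of 4 wild-type libraries either, and whether the gap reflects the island caller's threshold was not tested. The share of mitochondrial islands, a measure outside the comparisons, was 5.12 ± 2.67% of island reads in the Zfp36l1 knockdown and 2.43 ± 0.552% in its control (n = 3 each). Mitochondrial regions were among those tested, and the region M, 10801 to 16400, did not pass in this comparison (adjusted p = 1.00).

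The Rex1 knockdown gained 206 regions away from Zfp42, on 20 chromosomes, with a median width of 4.4 kb against 13.0 kb at Zfp42. Loss of Rex1 protein is argued against by the double knockout, which also lacks Rex1. At least 2 of its 3 libraries had an island at 18.4% of the regions (Wilson 95% interval 13.7 to 24.3%). This was near its wild type (17.96%, at least 2 of 4 libraries) and under the 50% that this explanation needs. The double knockout is, however, another line that also lacks Rnf12. A response to dCas9-KRAB with any guide or to abscisic acid is argued against by the design, since STC libraries received both. In the Zfp281 knockdown 22.3% of the regions (17.2 to 28.5%) had an island, under the 50% that this explanation needs. The F121.9 wild type, which received neither, had 17.96%, counted as at least 2 of 4 libraries rather than 2 of 3. The CasTuner controls of Rnf12 and Zfp280c, in TX1072 cells, had 20.9% and 12.1% (at least 2 of 3). The share of the Zfp280c control lay below the interval of the Zfp281 knockdown, so these groups give no single level for comparison. STC had 17.5%, but the regions were selected against STC, so its share gives no level for comparison. The level set beforehand to exclude either explanation, at most 10%, was wrong, since it lay below that of libraries without the cause. Rex1 guides binding elsewhere stays open, as does an effect of Rex1 loss in this line alone: no island lay in the other 6 split dCas9-KRAB libraries at 71.8% of the regions, but 3 of these are the STC libraries against which the regions were selected, which largely fixed that share, and guide sequences and a genome were not used here.

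Segments of chromosome 12 shifted as blocks in both knockout lines, while chromosome X between 10 and 70 Mb had medians of -0.28 to -0.67 in the Rnf12 knockout and of -0.05 to 0.11 in the double knockout. The tests used chromosome 12 alone. Library depth is argued against by the wild-type libraries, which held 1031064 to 3115479 island reads while their chromosome 12 contrast spanned 0.25 (log2). The lowest Rnf12 knockout library lay 0.76 above the highest wild-type library. The segments were picked from the difference between these groups, so this gap was partly built in, as was the 1.00 given next. Loss of Rnf12 by itself is argued against by the knockdown, where the same contrast moved by 0.0455 ± 0.0307 (SE) against 1.00 from wild type to knockout. The knockdown is, however, another line at day 3, and how much Rnf12 it lost was not measured here. A copy number or parental genome difference of whole segments may remain: 79.3% of 295 regions in the shifted segments were higher (Wilson 95% interval 74.3 to 83.6%), but the segments were picked from these values, so that test could not decide.

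Of the 12 imprinted regions that rose in the Rnf12 knockout, 9 were tested in the double knockout, a line that shares both the loss of Rnf12 and a history of derivation from the wild type, and 6 were called there, among them Meg3, in a chromosome 12 interval whose median rose by 0.79 in both lines. In the Rnf12 knockdown, 2 of the 12 positions held tested regions: 1 region at Igf2, at 0.40 (log2), and 4 within 1 region of Kcnq1 and Kcnq1ot1, with a median of 1.46. The median of these 5 was 0.57 (bootstrap 95% interval 0.09 to 3.78), all 5 lay above 0, and the other 10 positions held no tested region. The 5 regions lie at 2 positions and come from the same libraries, so they are not independent. Neither the interval nor the 5 above 0 measures the spread between samples. Neither loss of Rnf12 nor a difference that arose in culture is excluded by these values, and with 1 line per genotype they cannot be told apart.

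Other splits of the same libraries were tested for each count of changed regions. For the 6 knockdowns there are 10 splits, too few for a share under 0.05: the real values were 0, 0, 28, 0, 211 and 484 and the highest others 0, 0, 1, 0, 0 and 0 for Rnf12, Zic3, Zfp280c, Zfp36l1, Rex1 and Zfp281, and 10, 10, 1, 10, 1 and 1 splits gave as many. For Rnf12 knockout against wild type, 1 of 35 splits gave as many as 1151 (highest other 55), and for the double knockout against wild type 1 of 35 gave 377 (highest other 208, with wild-type replicates 1, 3 and 4 apart from the rest). Each share is 0.0286, under 0.05 and the smallest that 35 splits allow, so this count argues against chance for each comparison taken singly. With no adjustment over the 9 comparisons, it does not exclude chance. For the double knockout against the Rnf12 knockout 2 of 35 splits gave as many as 2, so chance may account for that count. Of these, 1 gave 99, with Rnf12 knockout replicates 2, 3 and 4 apart from the rest. Those replicates held 901805 to 1187790 island reads and the rest 1025266 to 3147241, and whether depth made that split was not tested.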

How the results depend on the processing

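Tests with chromosomes 12 and X left out, with mitochondrial islands or reads left out, and with replicates 2 and 3 alone were chosen only after the result was seen, and the estimated correlation was fixed beforehand with the design. Unless a reason is given, the cause was not tested.

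With DESeq2 the changed regions numbered 151 for Rnf12 knockdown, 125 for Zic3, 99 for Zfp280c, 582 for Rex1, 2237 for Zfp281, 2818 for Rnf12 knockout, 1252 for double knockout against wild type and 229 against Rnf12 knockout. Fitting the compared groups alone gave 0 for Zfp280c, 345 for Rex1, 1 for Zfp281, 605 for Rnf12 knockout and 159 for the double knockout against wild type. An island in every library gave 15 for Zfp280c, 30 for Rex1 and 861 for Zfp281, a filter that removes regions without an island in either group. RLE size factors gave 51 and library size alone 72 for Zfp280c, and library size alone 6 for Zfp36l1 and 4 for double against Rnf12 knockout, where no filterByExpr gave 6. RLE moved the median of all regions in the Zfp36l1 comparison from 0.01 to 0.13 (log2). A stricter caller gave 1 for Zic3, 715 for Rnf12 knockout and 1 for double against Rnf12 knockout, and 10 kb bins gave 5 for Zic3. Replicates 2 and 3 alone gave 0 for Zfp280c, with fewer libraries. Without chromosomes 12 and X the counts were 553, 197 and 1 in the F121.9 comparisons, where 748, 234 and 1 of the calls had lain on other chromosomes.

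The replicate number as a block gave 2 regions for Rnf12 knockdown, 888 for Zfp281 and 1 for double against Rnf12 knockout, and 2 called lists for Zfp281. For Rex1, camera with the block also called the X inactivation centre (adjusted p = 0.0272) and protocadherin clusters (adjusted p = 0.00206), both lower. Without the block each had an adjusted p of 0.0559. The naive pluripotency list was no longer called for Rex1. Every library correlated best with its own number in the Zic3, Rex1 and Zfp281 comparisons. The sign-flip test of the block kept the Xist difference of the Rnf12 knockout at 1.01 with an exact p of 0.125, the smallest that 4 pairs allow. With an estimated correlation the called lists fell to 0, 0, 0, 0, 2, 1, 2, 0 and 0, for the knockdowns of Rnf12, Zic3, Zfp280c, Zfp36l1, Rex1 and Zfp281, then Rnf12 knockout, double knockout against wild type and against Rnf12 knockout.

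Leaving out each library in turn gave 0 to 3 regions for Rnf12 knockdown (2 without knockdown replicate 1, 3 without control replicate 2), 0 to 22 for Zic3 (22 without knockdown replicate 3), 19 to 36 for Zfp280c, 29 to 177 for Rex1, 13 to 216 for Zfp281, 579 to 1376 for Rnf12 knockout, 107 to 583 for double knockout against wild type and 1 to 103 against Rnf12 knockout (103 without Rnf12 knockout replicate 1). The Xist difference of the Rnf12 knockout ranged from 0.86 to 1.11 and no longer passed 0.05, since 3 against 4 libraries cannot. It ranged from -0.39 to 0.27 for Zic3 (0.13 without knockdown replicate 3, 0.27 without control replicate 3) and from -0.32 to 0.0224 for Rex1 (the latter without STC replicate 2). In the Rlim gene body the Rnf12 knockout difference ranged from -0.46 to 0.51 (-0.01 and -0.46 without knockout replicates 2 and 3, -0.20 without wild-type replicate 1 or 3), and in the Rlim promoter the double knockout ranged from -0.0101 (without its replicate 3) to 1.47. The Zic3 region over the Xist start, at -0.14, turned to 0.0607 with the block, and ranged from -0.98 to 0.72 without single libraries (0.12 and 0.22 without knockdown replicates 2 and 3, 0.72 without control replicate 3).

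The Rlim promoter of the Rnf12 knockdown reversed to 0.74 with a 5 kb window, and the difference in island number of the Zfp280c knockdown to 270 with a stricter caller. The X share of the Rnf12 knockout as covered length was -1.18 points (exact permutation p = 0.0286). Regions gained or lost numbered 196 for Zfp280c and 256 for Zfp36l1 with a stricter caller, and 445 for Rnf12 knockout and 1670 for double against Rnf12 knockout with 50% of the region covered. Leaving out libraries they ranged from 2399 to 3013, 1966 to 3441, 706 to 2973, 886 to 2572, 3015 to 3386, 4190 to 4634, 935 to 1471, 1397 to 3918 and 1045 to 3976 in the order of the lists above, since fewer libraries must lack an island.

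Over the alternatives of the single regions that the rule names and of the list members that passed, calls were lost in 56 of 258 for Zfp280c, 32 of 211 for Rex1, 272 of 716 for Zfp281, 203 of 1021 for Rnf12 knockout, 123 of 597 for double knockout against wild type and 3 of 44 against Rnf12 knockout. Regions that had not passed came to pass in 7 of 94 for Rnf12 knockdown, 8 of 93 for Zic3, 2 of 100 for Zfp36l1 and 3 of 716 for Zfp281. Direction was kept in all of these except the Zic3 region over the Xist start, in 4 alternatives given above.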

Other observations

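The tests of shared wild-type libraries and of the housekeeping gene Pgk1 were chosen only after the result was seen.

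The Rnf12 knockout and the double knockout were compared with the same 4 wild-type libraries. Of 31979 regions tested in both, 728 rose in the Rnf12 knockout, 339 in the double knockout and 310 in both, where independent lists would share 7.72. Simulated libraries of an unchanged double knockout had 0 calls of their own over 20 draws, so they could share none and set no level for the overlap. With the wild-type libraries split in pairs, so that no library served in both comparisons, 65 to 130 regions were shared, where independent lists would share 1.18 to 3.14, and 2 to 3 of the 9 imprinted regions tested in both were called in both. Each genotype is 1 line, and the wild-type line itself may differ from both for reasons other than Rnf12, as the 6 imprinted regions called in both lines, of 9 tested in both and with Meg3 in a shifted segment of chromosome 12, also leave open.

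Pgk1, a glycolytic enzyme gene in the housekeeping list, held islands at its start (X, 106186601 to 106187200) in all 9 split dCas9-KRAB libraries, with 1061 ± 105 RPM in STC, 940 ± 348 in the Rex1 knockdown and 712 ± 135 in the Zfp281 knockdown (n = 3 each). In the CasTuner groups the means were 2.58 to 9.08 RPM, in the F121.9 wild type 0.722 RPM, and in the Rnf12 knockout and the double knockout no library had an island there. Whether these reads came from the gene itself or from a copy of its promoter elsewhere in these cells, such as in a construct, was not tested. The median housekeeping background in the split dCas9-KRAB experiment was 13.9 RPM per 4 kb with Pgk1 and 0.126 without it.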
